A study of Mus musculus with 12 samples.

How the data were processed

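The series holds 12 Affymetrix Mouse Gene 1.0 ST arrays of samples labelled as colon epithelial cells, with 3 arrays for each of 4 groups: WT on water, TG on water, WT on 4% DSS and TG on 4% DSS for 10 days. The deposited table holds 1 value for each of 28815 probe sets on each array, with no missing values. Per the submitters' processing notes, signals were summarised with RMA in Affymetrix Expression Console, whose versions are not given in the sources used here. The deposited values were taken as log2, the scale RMA returns, since the notes do not state the base. The median of each probe set over the 12 arrays was 0 to within 5e-07, so the deposited values are centred per probe set and hold differences between arrays and no absolute level. This centring was found from the values.

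Groups, comparisons, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The centring forced a departure from that design. A filter on dim probe sets and the choice of the brightest probe set per gene both need absolute levels, so no filter was applied and the probe sets of a gene were averaged, both of which had been listed as alternatives. Of the probe sets, 21780 were named by 1 gene symbol, 1605 by several and 5430 by none, and 21689 were matched through their gene identifiers to the RefSeq annotation of GRCm38.p6, which was used for names and for the order of genes along chromosomes. The probe sets with 1 symbol gave 19935 genes, of which 998 had several probe sets.

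The comparisons were DSS minus water in WT, TG minus WT at water, DSS minus water in TG, TG minus WT under DSS, and the interaction, which is the DSS change in TG minus that in WT. One linear model with a mean per group was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend and not robust, 8 residual degrees of freedom). P-values were two-sided and adjusted by Benjamini-Hochberg over the 19935 genes, and a gene passed at an adjusted p under 0.05 with no fold threshold. A permutation test of 3 against 3 arrays cannot give a p below 0.1, so no p-value was taken from one. Regroupings of the arrays were counted in the closing section. Tables and figures used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

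Gene lists numbered 42, with 943 entries of which 857 were measured. They covered epithelial cell types and functions, inflammation, metabolism, position along the gut, markers of other cell types and a check of sex. Each list was tested with camera at a preset correlation of 0.01, adjusted over the lists within a comparison. Beside it stood camera with a correlation estimated per list and fry, a self-contained rotation test. Members were counted as higher, lower or not passing over all genes, and again adjusted over the list alone.

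Named genes followed a rule. Cldn2 was always named. Of the genes that passed and whose groups of arrays did not overlap, the 8 with the largest positive and the 8 with the largest negative change were named, without predicted or non-descriptive symbols, and if none passed, the 5 with the smallest p. For each list that passed camera, and always for tight junction, cell cycle, cytokines and chemokines, and immune regulation and tolerance, up to 4 members with the smallest p could be named. Genes named in the observations outside this rule were chosen after their values were seen.

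The scripts were tested on simulated data with 67, 67 and 66 genes changed by 1, 2 and 4 log2 units. With a spread pooled over groups, 62.7%, 92.5% and 98.5% were recovered for DSS in WT, with 11 false calls. For TG against WT at water the shares were 77.6%, 92.5% and 98.5% with 12 false calls, for DSS in TG 70.1%, 91% and 98.5% with 9, and for TG against WT under DSS 73.1%, 89.6% and 97% with 10. When each group had the spread it has in the data, the false calls were 249, 28, 13 and 256 in the same order, so unequal spread raises false calls in the comparisons with the WT DSS arrays.

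Alternatives planned were a fit on the arrays of 2 groups alone, a replicate block, every probe set on its own, each array centred on its median, eBayes with trend and robust, weights per array, a threshold of 1.5-fold, an adjusted p under 0.01 and the omission of each array in turn. Added after the data were seen were weights per group, genes with a single probe set and the omission of WT DSS replicates 2 and 3 together. A filter by array medians, the brightest probe set and a further quantile normalization were planned and not run. Nothing was left out of the main analysis except the 7035 probe sets without a single gene name.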

Results

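The study asked how claudin-2 in the gut epithelium affects the colon at rest and during chemical injury. Claudin-2 is a tight junction protein that forms channels for small cations and water, and the mice carried a Villin-Claudin-2 transgene, named for villin, a protein of the epithelial brush border. Male transgenic mice (TG) and wild-type littermates (WT) drank water or 4% dextran sulfate sodium (DSS), a polymer that damages the colon lining, for 10 days. RNA labelled as coming from colon epithelial cells was hybridised to 12 Affymetrix mouse gene arrays, 3 for each of the 4 groups. The labels do not say that each array came from its own animal, so the p-values measure the spread between these samples, which may in part be technical. The fit pooled the spread of the 4 groups, so the SE of each comparison of 2 groups also drew on arrays it did not compare.

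Each value is a log2 signal relative to the median of the same probe set over the 12 arrays, so values compare arrays and give no absolute level. The arrays under DSS stood apart from one another. In WT DSS replicates 1, 2 and 3, 677, 3795 and 1035 of the 28815 probe sets lay more than 1 log2 unit from their own median. The counts were 285, 53 and 90 in TG DSS replicates 1, 2 and 3, and between 22 and 91 in the 6 water arrays. No pair of arrays held identical values. The small number of arrays limits the precision of every comparison.

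Cldn2 itself, the gene of the transgene, read -0.04, 0.02 and 0.11 in WT water replicates 1 to 3 and 0.36, 0.18 and -0.02 in TG water replicates 1 to 3. Under DSS it read -0.53, -2.28 and -0.12 in the WT arrays and -0.24, 0.27 and 0.15 in the TG arrays. TG exceeded WT at water by 0.14 ± 0.44 (SE, n = 3 arrays per group; limma adjusted p = 1) and under DSS by 1.04 ± 0.44 (limma adjusted p = 0.292), so neither difference passed. The SD of Cldn2 was 0.08 and 0.19 in the WT and TG water arrays and 1.15 in the WT DSS arrays, which raised the pooled SE. The difference under DSS drew most on WT DSS replicate 2, where the list of pan-epithelial genes had a median of -2.08. Whether the array's probes match the transgene's transcript is not known here, so Cldn2 checks the genotype labels only weakly.

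**Figure D1:**
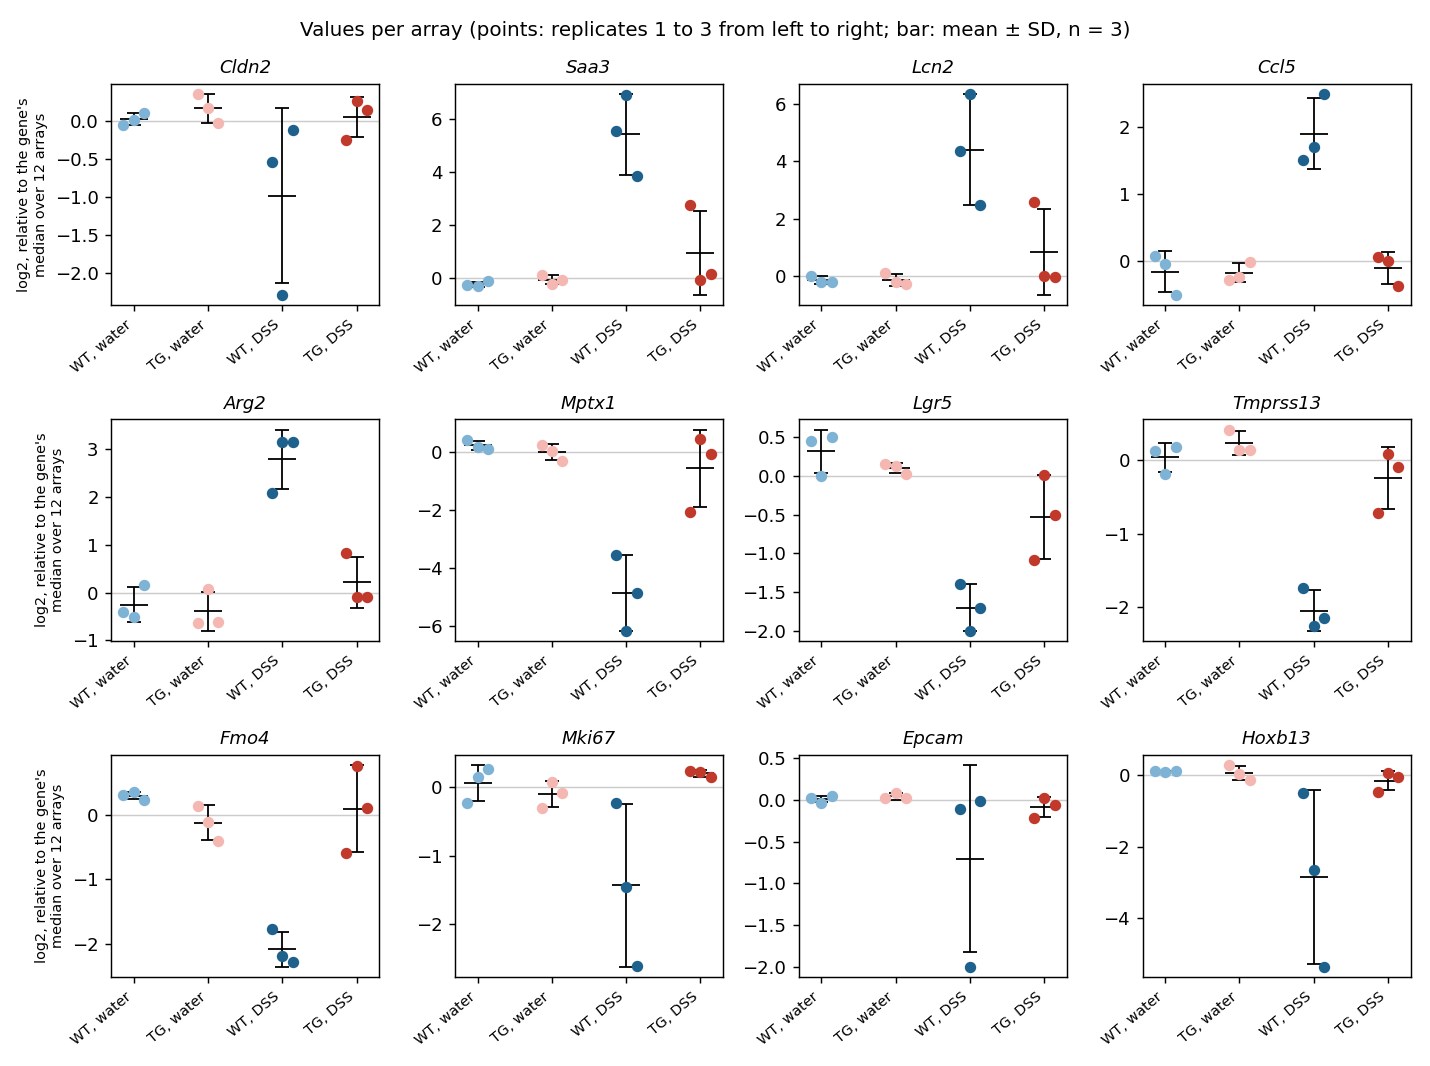
Values of 12 genes on each array, as log2 signal relative to the gene's median over the 12 arrays (vertical axis), for the 4 groups (horizontal axis). Points are replicates 1 to 3 from left to right and bars are mean ± SD with n = 3. Saa3 read 5.55, 6.89 and 3.83 in the 3 WT DSS arrays and 2.77, -0.10 and 0.15 in the 3 TG DSS arrays.

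The first comparison asked how WT epithelium responded to DSS. Saa3, an acute-phase protein made by injured epithelium and macrophages, rose by 5.67 ± 0.81 on the log2 scale (SE, n = 3 arrays per group; 50.8-fold; limma adjusted p = 0.0343). Arg2, the mitochondrial arginase, rose by 3.04 ± 0.36, and Ccl5, a chemokine that draws T cells, rose by 2.05 ± 0.25 (limma adjusted p = 0.0267 for both). Mptx1, a mucosal pentraxin, fell by 5.12 ± 0.69 (34.7-fold lower; limma adjusted p = 0.0285). Lgr5, the receptor that marks crypt base stem cells, fell by 2.01 ± 0.25 (limma adjusted p = 0.0267).

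The other named genes that rose in WT under DSS were Phf11d by 1.68 ± 0.23, Tm4sf4 by 1.28 ± 0.19, C2, a complement component, by 0.97 ± 0.13, Cyba, a subunit of the phagocyte NADPH oxidase, by 0.88 ± 0.13, and Sema6d by 0.84 ± 0.11. Their limma adjusted p-values lay between 0.0267 and 0.0373. Ttr, the thyroid hormone carrier transthyretin, fell by 2.69 ± 0.39 and Itih2 fell by 2.51 ± 0.32. Fmo4, a flavin monooxygenase, fell by 2.38 ± 0.29 and Slc6a4, the serotonin transporter, fell by 2.21 ± 0.34. Tmprss13, a membrane serine protease, fell by 2.09 ± 0.21 and Apobec2 fell by 1.95 ± 0.28. These 6 had limma adjusted p-values between 0.0214 and 0.0413. In total 34 of 19935 genes passed, 9 higher and 25 lower, and 3040 had an unadjusted p under 0.05 where 997 would by chance. For all 34 the 3 DSS arrays lay outside the range of the 3 water arrays, which held for 16.1% of all genes against 10% by chance.

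The spread differed between the groups. Arrays simulated with no difference but with each gene's own spread in each group gave 109 to 213 passing genes in 100 simulations, more than the 34 observed. The simulated genes were drawn independently, with spreads taken from 3 arrays each, so this range is no expected count for the real arrays. It shows only that unequal spread alone can make genes pass. No gene passed when only the 6 WT arrays were fitted or when each group had its own weight. Without WT DSS replicate 1, 2 or 3 the count was 919, 92 and 575, without 1 array of the other groups it lay between 0 and 83. Leaving out both WT DSS replicates 2 and 3, chosen after seeing the data, gave 158, of which 12 were among the 34. That fit kept 1 WT DSS array and took its spread from the other groups, so its count tests nothing about WT DSS.

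Gene lists fixed before the data were examined were tested with camera, and in WT under DSS 17 of 42 rose and 9 fell. None of the 26 passed with an estimated correlation, where their adjusted p-values lay between 0.168 and 0.552. That correlation was 0.956 for pan-epithelial, 0.885 for fibroblast and 0.77 for cell cycle genes, but 0.003 for the crypt base stem cell list. Where it lies far above the preset 0.01, camera at the preset value passes lists too readily. Inflammatory lists rose. The cytokines and chemokines had a median of 1.16 over 35 measured genes (camera adjusted p = 2.11e-13; adjusted p = 0.225 with an estimated correlation). Of these, 1 passed over all genes, and adjusted over the list alone 14 were higher and 1 lower. The array medians of the list were 0.82, 1.78 and 0.08 in WT DSS replicates 1 to 3. Its examples beside Ccl5 were Tnf at 1.54 ± 0.25, Cxcl2 at 4.41 ± 0.75 and Ccl3 at 4.21 ± 0.85, which did not pass over all genes (limma adjusted p = 0.0511, 0.0618 and 0.0751). The antimicrobial and acute-phase list rose with a median of 0.68 (adjusted p = 0.168 with an estimated correlation). Of its 26 genes 1 passed over all genes and 10 adjusted over the list alone, and Lcn2, which binds bacterial iron carriers, stood at 4.54 ± 0.90. The immune regulation and tolerance list rose with a median of 0.75 over 31 genes (adjusted p = 0.202 with an estimated correlation), of which 1, Arg2, passed over all genes and 8 adjusted over the list alone. Arg1 stood at 1.32 ± 0.29 and Cd274, which encodes the checkpoint ligand PD-L1, at 1.19 ± 0.32.

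Matrix remodelling genes rose in WT under DSS, with a median of 1.63 and all 23 above 0, although 0 passed over all genes and 12 adjusted over the list alone (adjusted p = 0.316 with an estimated correlation). Their array medians were 1.46, 3.07 and 0.08 in WT DSS replicates 1 to 3. Mmp13, a collagenase, stood at 4.77 ± 1.04 and Mmp3 at 3.97 ± 0.91. The interferon response list rose with a median of 0.48, MHC class II with 0.27, the pattern recognition and NF-kB list with 0.41, the immediate early list with 0.58 and the epithelial repair list with 0.22. With an estimated correlation the adjusted p-values of these 5 lists were 0.355, 0.552, 0.202, 0.424 and 0.355. No member passed over all genes, and adjusted over the list alone 9 passed in the pattern recognition list, 3 in the epithelial repair list and 0 in the other 3. The unfolded protein response list rose by little, with a median of 0.11 (adjusted p = 0.168 with an estimated correlation) and 5 of 22 genes higher adjusted over the list alone, among them the chaperone gene Hspa5 at 0.42 ± 0.10.

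Markers of several other cell types rose in the same arrays. The neutrophil list had a median of 1.89, macrophages and monocytes 1.13, endothelium 1.04, fibroblasts 0.81, T and NK cells 0.33 and enteric neurons and glia 0.31. Their adjusted p-values with an estimated correlation were 0.316, 0.355, 0.438, 0.443, 0.335 and 0.424. No member passed over all genes. Adjusted over the list alone 15 neutrophil genes were higher and 1 lower, with 7 macrophage, 2 T and NK cell and 1 enteric neuron gene higher. WT DSS replicate 2 led these lists, with array medians of 3.53 for neutrophil, 2.39 for macrophage and 2.89 for endothelium genes. The medians were 1.49, 1.11 and 0.62 in WT DSS replicate 1, and 0.24, -0.08 and -0.24 in replicate 3. Smooth muscle and adipocyte markers did not pass, with medians of -0.212 and -0.235 for DSS in WT. The smooth muscle array medians were -0.961, 0.655 and 0.125 in WT DSS replicates 1 to 3.

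Several epithelial lists fell in WT under DSS. The tuft cell list rose, with a median of 0.06 (adjusted p = 0.516 with an estimated correlation), 0 members passing either way and array medians of -0.09, -0.01 and 0.33 in WT DSS replicates 1 to 3. The enteroendocrine and goblet cell lists did not pass, with medians of 0.18 and -0.39. The absorptive colonocyte list had a median of -0.85, with 0 of 29 genes passing over all genes and 10 lower adjusted over the list alone (adjusted p = 0.489 with an estimated correlation), and Scnn1a, a subunit of the epithelial sodium channel, stood at -1.95 ± 0.39. The pan-epithelial list fell with a median of -0.76 and the tight junction list with -0.45, with 0 genes passing either way (adjusted p = 0.552 and 0.516 with an estimated correlation), and Cldn12 stood at -0.61 ± 0.23 and Tjp1 at -0.20 ± 0.09 (limma adjusted p = 0.253 and 0.315). WT DSS replicate 2 had array medians of -2.08 for pan-epithelial, -1.94 for tight junction and -2.32 for absorptive colonocyte genes. Replicates 1 and 3 had -0.09 and 0.05 for pan-epithelial genes. The crypt base stem cell and Wnt target list fell with a median of -0.29, with Lgr5 passing over all genes, and adjusted over the list alone 9 of 20 were lower and 1 higher (adjusted p = 0.168 with an estimated correlation). Its member Ascl2 stood at -1.28 ± 0.23 and Axin2 at -0.95 ± 0.18. Fry, a rotation test of whether a list moves one way on balance, passed this list (adjusted p = 0.00796) and 6 others, namely unfolded protein response, posterior Hox, circadian clock, cytokines, antimicrobial and immune regulation, with adjusted p-values up to 0.0453.

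Cell cycle genes fell with a median of -0.59 in WT under DSS, with 0 of 33 passing over all genes and 14 lower adjusted over the list alone (adjusted p = 0.489 with an estimated correlation). Their array medians were 0.06, -0.68 and -1.38 in WT DSS replicates 1 to 3. Posterior Hox genes, which mark the hind part of the gut, fell with a median of -0.63 (adjusted p = 0.316 with an estimated correlation), with 0 of 11 passing over all genes and 6 lower adjusted over the list alone, and Hoxb13 read -0.50, -2.65 and -5.36 in the 3 WT DSS arrays. The anterior Hox list, which did not pass here, had a median of 0.58 in WT DSS replicate 3 and of 0.00 and 0.01 in replicates 1 and 2. Circadian clock genes fell with a median of -0.42 (adjusted p = 0.316 with an estimated correlation). Adjusted over the list alone 9 of the 18 clock genes were lower and 2 higher, with 0 passing over all genes, and Dbp stood at -1.78 ± 0.37 while Nfil3 stood at 1.78 ± 0.32. Oxidative phosphorylation fell with a median of -0.34 and cholesterol synthesis with -0.37 (adjusted p = 0.489 and 0.516 with an estimated correlation), with 0 members of either passing over all genes and 1 and 0 adjusted over the list alone. WT DSS replicate 2 carried most of both falls, with array medians of -0.11, -0.81 and 0.00 for oxidative phosphorylation and 0.01, -0.89 and -0.22 for cholesterol synthesis in WT DSS replicates 1 to 3.

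**Figure D2:**
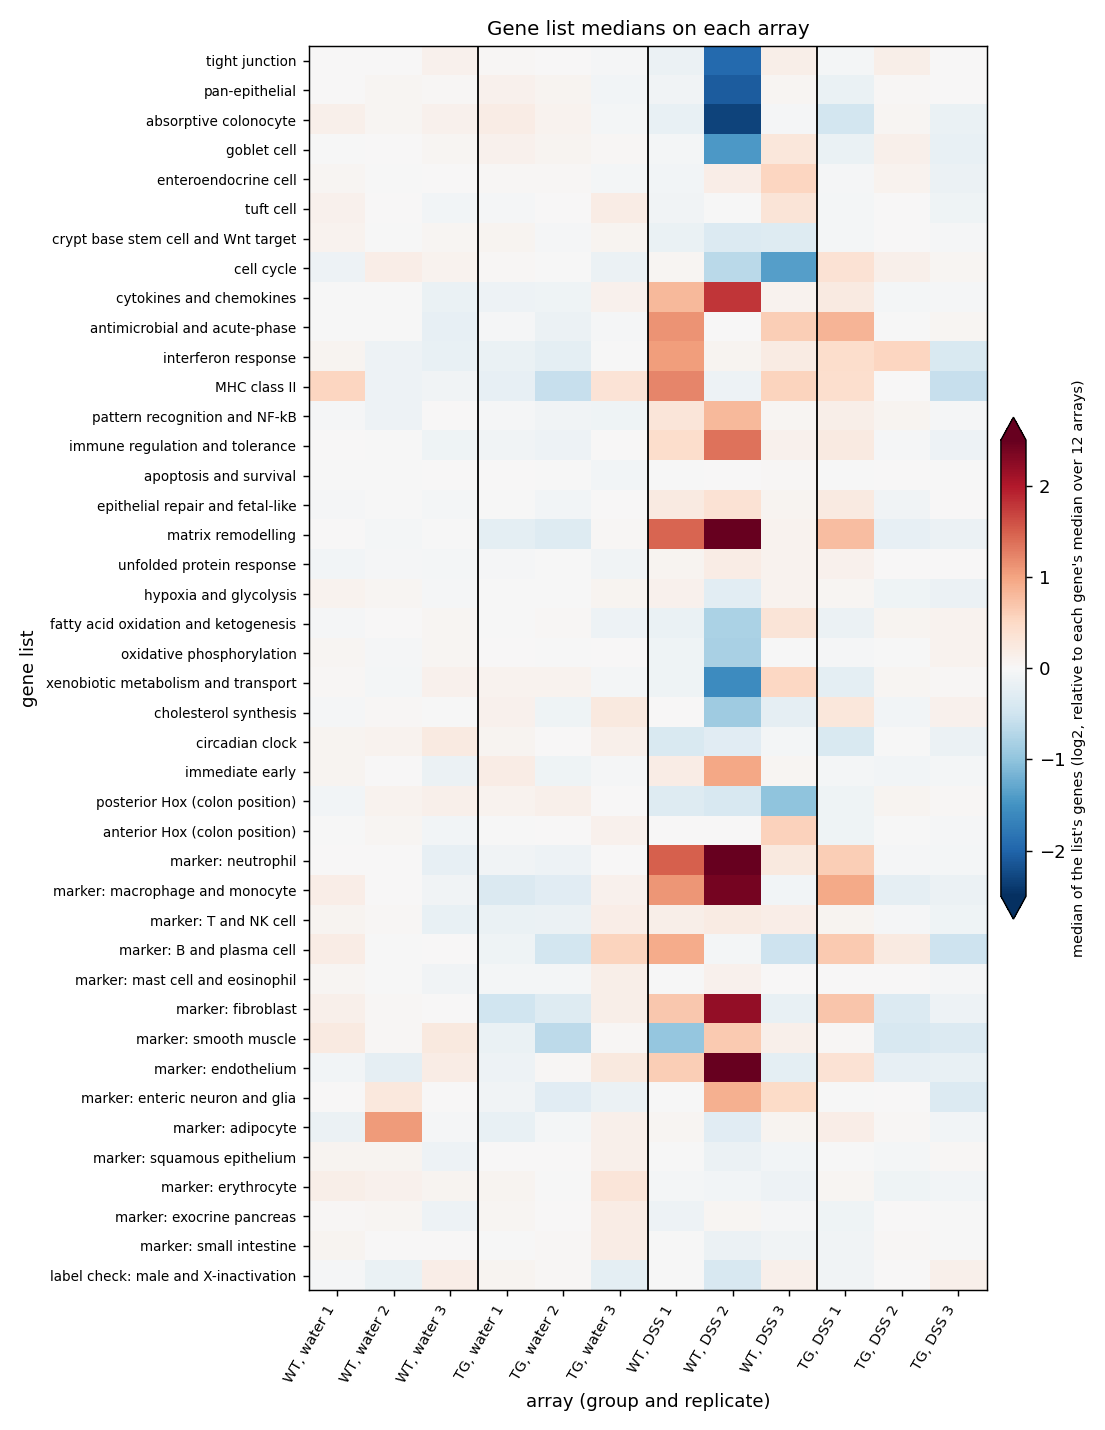
Median of each gene list (vertical axis) on each of the 12 arrays (horizontal axis, by group and replicate), in log2 relative to each gene's median over the 12 arrays; red is above and blue below that median. The strongest colours lie in WT DSS replicate 2, where the neutrophil median is 3.53 and the absorptive colonocyte median -2.32.

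The second comparison asked what the transgene did without injury. No gene passed at water in limma, and 61 had an unadjusted p under 0.05 where 997 would by chance. That count depended on the pooled spread, which includes the WT DSS arrays. With the 2 water groups fitted alone it was 423, and with weights per group 141, with 0 genes passing in both. The 5 genes with the smallest p-values were Usp17ld at 0.46 ± 0.11, Rbp2, a retinol carrier of enterocytes, at -1.42 ± 0.39, Foxred1 at -0.55 ± 0.15, Entpd4 at -0.33 ± 0.09 and Tnfaip8 at 0.24 ± 0.07 in TG minus WT (SE, n = 3 arrays per group), each with a limma adjusted p of 1. Rbp2 read 0.98, 0.98 and 1.35 in the WT water arrays and -0.19, -0.35 and -0.41 in the TG water arrays. Its SD was 0.21 and 0.11 in these groups and 0.95 in the WT DSS arrays, which raised its pooled SE. Foxred1 read 0.35 in TG DSS replicate 2, beside -0.14 and -0.22 in replicates 1 and 3 and -0.30 to -0.27 in the TG water arrays. The groups did not overlap for 4.98% of genes, against 10% by chance.

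At water 6 of 42 lists were lower in TG by camera, and no list was higher. They were markers of smooth muscle with a median of -0.42, enteric neurons and glia with -0.37, adipocytes with -0.32, fibroblasts with -0.25 and macrophages with -0.23, and MHC class II with -0.39. None passed with an estimated correlation (adjusted p = 0.958 for each), and 0 members passed over all genes or adjusted over the list alone. The adipocyte median was 1.06 in WT water replicate 2 and between -0.19 and 0.12 in the other 5 water arrays, and without that array the list no longer passed, with a median of 0.05. MHC class II medians were 0.55, -0.13 and -0.08 in WT water replicates 1 to 3 and -0.20, -0.58 and 0.34 in TG water replicates 1 to 3. In TG water replicate 3 the fibroblast and macrophage medians were 0.14 and 0.10, against 0.00 to 0.13 and -0.09 to 0.17 in the WT water arrays. Tight junction genes had a median near 0 on each water array, from -0.02 to 0.10. Of the cell cycle list Aurkb stood at -0.22 ± 0.34, of the cytokines Cxcl16 at -0.30 ± 0.31 and of the immune regulation list Lgals1 at -0.42 ± 0.39 (limma adjusted p = 1 for each). With weights per array limma passed 1971 genes at water, and in every other setting tried 0.

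The third comparison asked how TG epithelium responded to DSS. No gene passed in limma, and 475 had an unadjusted p under 0.05 where 997 would by chance. That count depended on the pooled spread, which includes the WT DSS arrays. With the 2 TG groups fitted alone it was 1126, and with weights per group 1206, with 0 genes passing in both. A count below chance in the main fit is therefore no measure of a missing response in TG. The 5 smallest p-values belonged to Mgst1, a microsomal glutathione transferase, at 0.53 ± 0.09, Fbxo32, a ubiquitin ligase subunit, at -0.49 ± 0.10, Qpct at -1.13 ± 0.23, Rilpl2 at 0.56 ± 0.12 and Klk15 at -1.32 ± 0.29 in DSS minus water (SE, n = 3 arrays per group; limma adjusted p = 1 for each). The groups did not overlap for 13.4% of genes, against 10% by chance. TG DSS replicate 1 differed from the other replicates of its group. Saa3 read 2.77, -0.10 and 0.15 in TG DSS replicates 1 to 3, Lcn2 read 2.58, -0.01 and -0.03, and Lgr5 read -1.08, 0.00 and -0.51.

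In TG under DSS 7 of 42 lists rose and 5 fell by camera, none of them with an estimated correlation, and no member of these 12 lists passed over all genes or adjusted over the list alone. Interferon response genes rose with a median of 0.44 and antimicrobial genes with 0.48 (adjusted p = 0.752 for both with an estimated correlation). Stat2 stood at 0.42 ± 0.18, Psmb8 at 0.46 ± 0.21 and Retnlb, an epithelial antimicrobial protein, at 2.06 ± 0.81. Cell cycle genes rose with a median of 0.24, pattern recognition genes with 0.12, matrix remodelling with 0.30, macrophage markers with 0.37 and fibroblast markers with 0.33 (adjusted p = 0.993 for each with an estimated correlation). Except for interferon response genes, the rises were largest in TG DSS replicate 1. In TG DSS replicates 1 to 3 the array medians were 0.77, -0.21 and -0.16 for matrix remodelling, 0.95, -0.22 and -0.15 for macrophages, 0.70, -0.34 and -0.14 for fibroblasts and 0.86, -0.01 and 0.04 for antimicrobial genes. They were 0.37, 0.12 and 0.06 for cell cycle, 0.15, 0.07 and -0.02 for pattern recognition and 0.43, 0.53 and -0.38 for interferon response genes. Mcm6, part of the replicative helicase, stood at 0.69 ± 0.41 and Mmp3 at 1.97 ± 0.91. Circadian clock genes fell with a median of -0.30 (adjusted p = 0.474 with an estimated correlation), with Per1 at -0.55 ± 0.23 and Dbp at -0.85 ± 0.37. Absorptive colonocyte genes fell with a median of -0.27 and hypoxia and glycolysis genes with -0.09 (adjusted p = 0.993 for both with an estimated correlation), with Scnn1g at -1.30 ± 0.44 and Pgam1 at -0.30 ± 0.09. In TG DSS replicates 1 to 3 absorptive colonocyte genes had array medians of -0.45, 0.06 and -0.17, and without replicate 1 that list no longer passed, with a median of -0.15. Clock genes had -0.38, -0.01 and -0.15 and hypoxia genes 0.04, -0.11 and -0.15. Erythrocyte and pancreas markers, with 4 and 14 measured genes, had medians of -0.18 and -0.13 (adjusted p = 0.474 and 0.752 with an estimated correlation). In TG DSS replicates 1 to 3 the array medians were 0.04, -0.115 and -0.078 for erythrocyte and -0.104, 0.011 and -0.008 for pancreas genes. In TG water replicates 1 to 3 they were 0.065, -0.011 and 0.305, and 0.05, 0.013 and 0.178. Of the lists always described, Cldn10 of the tight junction list stood at 0.19 ± 0.14, Tnf of the cytokines at 0.60 ± 0.25 and Socs3 of the immune regulation list at 0.82 ± 0.46.

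Leaving out TG DSS replicate 1, TG water replicate 1 or TG water replicate 2 moved the number of lists that passed in TG under DSS from 12 to 5, 5 and 7. With weights per array limma passed 4 genes, and in every other setting tried 0.

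The fourth comparison asked how the genotypes differed under DSS. Fmo4 was higher in TG than in WT by 2.17 ± 0.29 on the log2 scale (SE, n = 3 arrays per group; limma adjusted p = 0.0479), Tmprss13 by 1.81 ± 0.21 and Stk26 by 1.79 ± 0.23 (limma adjusted p = 0.0413 for both). Gstm7, a glutathione transferase, was higher by 1.11 ± 0.15 and Tmeff1 by 0.95 ± 0.12, with Trp53i11 at 0.90 ± 0.09 and Tmem40 at 0.71 ± 0.09 (limma adjusted p between 0.0331 and 0.0479). Ccl5 was lower in TG, at -1.99 ± 0.25 (limma adjusted p = 0.0413). These 8 genes, 7 higher and 1 lower, were all that passed, and 3178 had an unadjusted p under 0.05 where 997 would by chance. The 3 TG DSS arrays did not overlap the 3 WT DSS arrays in any of the 8, nor in 19% of all genes, against 10% by chance.

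Of the 8 genes, 7 were also among the 34 that passed between water and DSS in WT, with the opposite sign. Both comparisons use the 3 WT DSS arrays. Independent lists of these sizes would share 0.0092 genes with opposite sign. Simulated arrays with no difference shared 75 to 155 genes, out of 95 to 225 passing under DSS, which exceeds the 8 observed. Part of the overlap may therefore come from the shared arrays. These simulations too drew genes independently with spreads from 3 arrays each, so they give no expected size for the real overlap.

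No gene passed under DSS when only the 6 DSS arrays were fitted, with 1 weight per group, or without any 1 of TG DSS replicates 2 and 3, WT water replicates 1 to 3 and TG water replicates 1 and 2, and 2 passed without TG water replicate 3. Without WT DSS replicate 1, 2 or 3 the count was 1166, 16 and 164, and with each array centred on its median it was 4, with 3 higher and 1 lower. Without both WT DSS replicates 2 and 3 it was 56, of which 3 were among the 8, and this count too rested on 1 WT DSS array.

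By camera 8 lists were higher and 19 lower in TG than in WT under DSS, and none passed with an estimated correlation, where their adjusted p-values lay between 0.374 and 0.723. Cell cycle genes were higher with a median of 0.80 and all 33 above 0 (adjusted p = 0.374 with an estimated correlation). None passed over all genes and 17 were higher adjusted over the list alone, among them Kif20a at 1.46 ± 0.34, Ccnb2 at 1.80 ± 0.42 and Aurkb at 1.40 ± 0.34. The array medians of cell cycle genes were 0.06, -0.68 and -1.38 in WT DSS and 0.37, 0.12 and 0.06 in TG DSS replicates 1 to 3. Those of posterior Hox genes were -0.327, -0.406 and -0.998 in WT DSS and -0.11, 0.06 and 0.03 in TG DSS. The crypt base stem cell and Wnt target list was higher with a median of 0.33 (adjusted p = 0.374 with an estimated correlation). Adjusted over the list alone 10 of its 20 genes were higher and 1 lower, with 0 passing over all genes, and Lgr5 stood at 1.17 ± 0.25. It was the 1 list that fry passed (adjusted p = 0.013). Pan-epithelial genes were higher with a median of 0.62, absorptive colonocyte genes with 0.58 and tight junction genes with 0.40 (adjusted p = 0.629, 0.723 and 0.616 with an estimated correlation), with 0 members passing over all genes or adjusted over the list alone. Without WT DSS replicate 2 these 3 medians were -0.02, -0.20 and 0.03 and none of the 3 lists passed. Oxidative phosphorylation stood at 0.36, cholesterol synthesis at 0.47 and posterior Hox at 0.60 (adjusted p = 0.537, 0.453 and 0.374 with an estimated correlation). Adjusted over the list alone 1, 1 and 3 of their members were higher.

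Inflammatory lists were lower in TG than in WT under DSS. Matrix remodelling genes had a median of -1.56 and cytokines and chemokines -0.96, with Cxcl2 at -4.09 ± 0.75 and Ccl3 at -3.69 ± 0.85 (limma adjusted p = 0.0882 and 0.123). Immune regulation and tolerance genes had a median of -0.63, with Arg2 at -2.58 ± 0.36 (limma adjusted p = 0.0658). The antimicrobial list had -0.22, with Saa3 at -4.49 ± 0.81 (limma adjusted p = 0.0855), the immediate early list -0.62 and the pattern recognition list -0.33. All 6 lists had an adjusted p of 0.374 with an estimated correlation. The interferon response list stood at -0.16, MHC class II at -0.61 and the epithelial repair list at -0.21 (adjusted p = 0.594, 0.458 and 0.453 with an estimated correlation). Of the cytokines 1 passed over all genes, and adjusted over the list alone 11 were lower and 1 higher. The arrays of the genotypes overlapped in several of these lists. The medians in WT DSS replicate 3 were 0.08 for matrix remodelling and 0.08 for cytokines, below the 0.77 and 0.23 of TG DSS replicate 1, and those of WT DSS replicates 1 and 2 were 1.46 and 3.07, and 0.82 and 1.78. The interferon medians were 1.05, 0.07 and 0.20 in WT DSS and 0.43, 0.53 and -0.38 in TG DSS replicates 1 to 3. In the other 8 lists 0 members passed over all genes. Adjusted over the list alone 2 members each were lower in the antimicrobial, immune regulation and epithelial repair lists, and 1 epithelial repair gene was higher.

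Neutrophil markers were lower in TG under DSS with a median of -1.71, macrophages with -1.04, enteric neurons and glia with -0.70 and T and NK cells with -0.25 (adjusted p = 0.374 for each with an estimated correlation). Endothelium had -1.08 and fibroblasts -0.85 (adjusted p = 0.453 and 0.458 with an estimated correlation). Tuft cells had -0.20, enteroendocrine cells -0.31, the unfolded protein response -0.08 and anterior Hox genes -0.27 (adjusted p = 0.374, 0.374, 0.374 and 0.453 with an estimated correlation). Against the enteroendocrine list Neurog3 stood at 0.74 ± 0.25 and Reg4 at 1.51 ± 0.53. In these 10 lists 0 members passed over all genes. Adjusted over the list alone 11 neutrophil genes were lower and 2 higher, 6 enteric neuron genes were lower, and 3 anterior Hox genes were lower and 2 higher. WT DSS replicate 2 carried most of the difference in endothelium and fibroblasts, with array medians of 0.62, 2.89 and -0.24 and of 0.68, 2.19 and -0.19 in WT DSS replicates 1 to 3. Without it the medians of the comparison were -0.24 for endothelium, -0.23 for fibroblasts, -0.75 for neutrophils, -0.68 for matrix remodelling and -0.33 for cytokines, and these 5 lists still passed.

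The interaction asked whether the change under DSS itself differed between the genotypes. No gene passed, the smallest limma adjusted p was 0.797, and 1167 genes had an unadjusted p under 0.05 where 997 would by chance. The 5 smallest p-values belonged to Fmo4 at 2.59 ± 0.41, Trp53i11 at 0.81 ± 0.13, Ccl5 at -1.97 ± 0.35, Tmeff1 at 0.90 ± 0.16 and Tmprss13 at 1.62 ± 0.30 for the change in TG minus that in WT (SE, n = 3 arrays per group; limma adjusted p = 0.797 for each). Saa3 stood at -4.65 ± 1.14, Arg2 at -2.44 ± 0.51 and Lgr5 at 1.38 ± 0.36, and none of the 3 passed. Without WT DSS replicate 1 the count was 239, without replicate 3 it was 6 and without both replicates 2 and 3, with 1 WT DSS array left, it was 22.

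By camera the change under DSS was higher in TG for 8 lists and lower for 15, none of them with an estimated correlation (adjusted p between 0.452 and 0.72). Among the higher lists were cell cycle genes with a median of 0.91, pan-epithelial genes with 0.67, posterior Hox genes with 0.63, absorptive colonocyte genes with 0.62 and tight junction genes with 0.40. With an estimated correlation their adjusted p-values were 0.498, 0.72, 0.452, 0.72 and 0.557. Among the lower lists were neutrophil markers with -1.59, matrix remodelling with -1.49, endothelium with -1.14 and cytokines with -0.81 (adjusted p = 0.498, 0.545, 0.557 and 0.452 with an estimated correlation). In these 23 lists 0 members passed over all genes, and adjusted over the list alone 4 crypt base stem cell genes were higher, with 2 cytokines and 1 immune regulation gene lower. Without WT DSS replicate 2 the medians of pan-epithelial and absorptive colonocyte genes were 0.00 and -0.13 and neither list passed. Neutrophil markers then had -0.75, matrix remodelling -0.65, endothelium -0.25 and cytokines -0.30, and these 4 still passed, while fibroblasts had 0.04 and no longer passed.

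Set side by side across the 19935 genes, the DSS changes of the genotypes correlated with Pearson r = 0.384 and Spearman rho = 0.239, and genes are not independent replicates. The fitted changes had an SD over genes of 0.18 in TG against 0.457 in WT, with a major-axis slope of 0.174. These measures include the spread between arrays, which was larger in WT DSS, so they do not show by themselves a smaller response in TG. The TG mean also joined unlike arrays, as TG DSS replicates 2 and 3 correlated best with TG water replicates 1 and 2 (r = 0.339 and 0.401). Of the 34 genes that passed in WT, 33 had the same sign in TG and all 34 were smaller there, with a median size of 0.21 against 1.17. Genes picked for large changes in WT tend to be smaller in any other set, and no gene passed the test of the difference. Without TG DSS replicate 1 the correlation was 0.007, so it rested on that array.

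**Figure D3:**
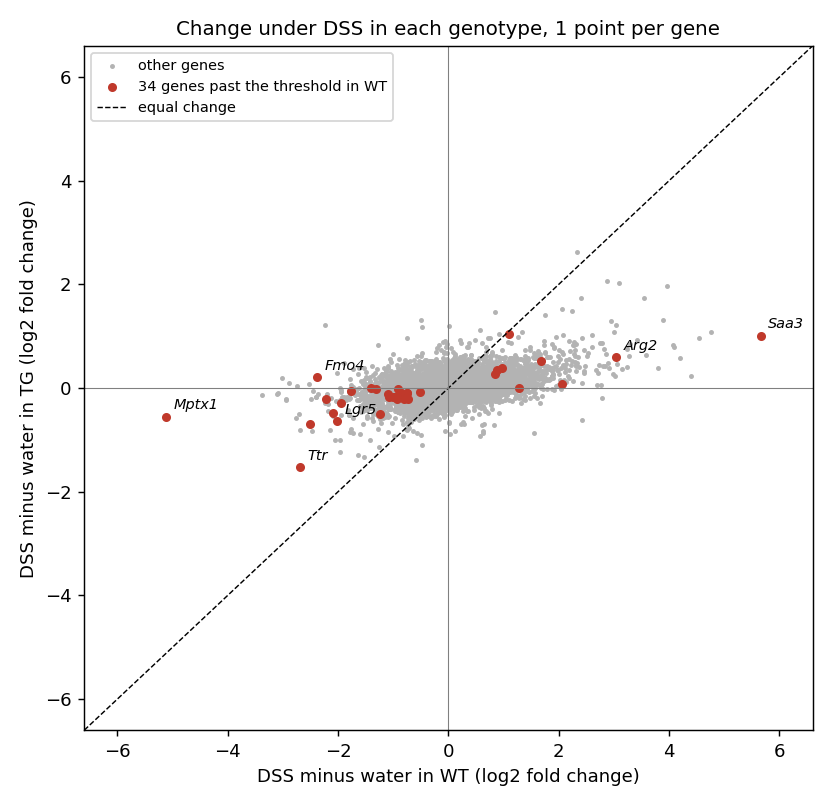
Log2 fold change under DSS in WT (horizontal axis) and in TG (vertical axis), 1 point per gene, with the 34 genes that passed in WT in red and equal change as a dashed line. The red points lie closer to 0 on the vertical axis than on the horizontal one, as for Saa3 with 5.67 in WT and 1.01 in TG.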

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

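In this part the tests of WT DSS replicate 2, of WT DSS replicate 3 and of antigen-presenting cells were chosen only after the result was seen, and the splits of the arrays and the test of the MHC haplotype were written down before they were run.

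No list passed for the interaction with an estimated correlation, where the smallest adjusted p was 0.452. By camera with the preset correlation the change under DSS was lower in TG for neutrophils (-1.59), matrix remodelling (-1.49), endothelium (-1.14), cytokines and chemokines (-0.81), macrophages (-0.75), immediate early genes (-0.62), immune regulation (-0.62), fibroblasts (-0.57), anterior Hox (-0.34), T and NK cells (-0.31), enteric neurons and glia (-0.30), pattern recognition (-0.29), antimicrobial genes (-0.28), tuft cells (-0.25) and the unfolded protein response (-0.12). It was higher in TG for cell cycle (0.91), pan-epithelial (0.67), posterior Hox (0.63), absorptive colonocyte (0.62), cholesterol synthesis (0.40), tight junction (0.40), oxidative phosphorylation (0.38) and crypt base stem cell genes (0.37). With genotype labels permuted within each treatment, 18 of 100 splits called at least as many lists as the 23 observed, up to 28, so chance cannot be excluded for that count. For genes the observed count was 0, which any split reaches (100 of 100, up to 1), so the splits say nothing about it.

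The other comparisons allow 10 splits, too few to exclude chance. For DSS in WT the real grouping gave 34 genes and the highest other split 0, with 1 of 10 as large. For lists it was 26 against 25, with 1 of 10, and the other splits ran from 13 to 25. For TG at water it was 6 lists against 9, with 3 of 10, and for DSS in TG 12 lists against 20, with 5 of 10. For genes both had a real count of 0, which any split reaches (10 of 10), so the splits say nothing there. For TG under DSS it was 8 genes against 87, with 2 of 10, and 27 lists against 25, with 1 of 10. The split with 87 genes set WT DSS replicates 1 and 2 and TG DSS replicate 1 against the other 3 DSS arrays, which points to a structure of the samples other than genotype.

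Of the probe sets without a single gene name, 6 passed for DSS in WT, all higher, among 49 that passed when every probe set was tested. For TG under DSS 1 passed, which was lower, among 5.

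The first pattern is WT DSS replicate 2, with epithelial genes low and markers of several other cells high. A lower share of epithelial cells alone would raise all other cell types alike, which is argued against by a B and plasma cell median of -0.046 beside a neutrophil median of 3.53. A shift of the whole array would move all lists the same way. As the sole explanation it is argued against by medians of -2.08 for pan-epithelial genes beside 3.53 for neutrophil and 2.89 for endothelium genes. The median over all genes of -0.055 is held near 0 by normalization and centring, so it tests nothing here. That 100% of the 17 pan-epithelial genes lay under -1 on this array restates the pattern and tests no explanation. Fewer epithelial cells with a changed makeup of the other cells, through DSS or through the isolation of cells, stays open.

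The second pattern is WT DSS replicate 3, where posterior Hox genes were low, with Hoxb13 at -5.36 and Hoxd13 at -4.26. Tissue from another position along the gut may explain it, since the anterior Hox median was 0.581, although Hoxa3, Hoxa5 and Hoxa7 read -0.66, -0.75 and -1.26. The small intestine genes Sis, Alpi and Slc10a2 read 3.62, 3.71 and 3.08, while the 16 other genes of that list had a median of -0.105. The list as a whole thus did not rise. Those 3 genes were set aside after their values were seen, so the median cannot exclude small intestine cells that express only part of the list. An effect of DSS on Hox genes was not tested and stays open.

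The third pattern is H2-Ea, an MHC class II gene, at -3.62 in WT water replicate 1 and -3.70 in WT DSS replicate 3. Fewer antigen-presenting cells would lower the MHC class II list, whose medians were 0.546 and 0.566 in these arrays. That list holds genes such as H2-Ab1 that another haplotype could itself shift, so it cannot decide. In the same order the B and plasma cell medians were 0.19 and -0.513 and the macrophage medians 0.169 and -0.075. Another MHC haplotype may explain it, as mice of the b haplotype do not transcribe H2-Ea. A test of the genes near H2-Ea left out H2-Ea, H2-Q2, H2-Q4, H2-Ab1 and the MHC class II list. In WT water replicate 1 and WT DSS replicate 3, H2-Q2 read 1.51 and 2.88, H2-Q4 -1.52 and -1.04, and H2-Ab1 1.24 and 1.59. In WT DSS replicate 1, H2-Q2 and H2-Ab1 also read 0.99 and 1.44. Among the 100 other genes nearest H2-Ea, 3 (Wdr46, Btnl5-ps and Ly6g6e) deviated by over 0.5 the same way in both arrays. Of 17910 windows 1.12% reached as many. These deviations were not all particular to the 2 arrays. Ly6g6e read -0.52 and -1.90 in WT DSS replicates 1 and 2, where H2-Ea read 0.69 and -0.07, and Btnl5-ps read 0.61 and -1.53 there. H2-Ea itself also read -1.63 in TG DSS replicate 3. No sequence was read, so another haplotype remains a hypothesis.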

How the results depend on the processing

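Weights per group, single probe set genes and leaving out WT DSS replicates 2 and 3 together were added after the data were seen. Not run were a filter on dim probes by array medians, the brightest probe set per gene and a second quantile normalization, since the values are centred; no filter and the mean over probe sets became the main setting for that reason. Unless said otherwise the cause of a change was not tested.

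The counts of genes that passed were 34 for DSS in WT, 0 for TG at water, 0 for DSS in TG, 8 for TG under DSS and 0 for the interaction. Fitting 2 groups alone gave 0 for DSS in WT and 0 for TG under DSS, as did an adjusted p under 0.01 and weights per group. Trend and robust together gave 2 and 0. The trend was fitted against each gene's mean of the centred values, which holds no absolute level, so these 2 counts are no sound check. Testing every probe set gave 5 for TG under DSS and centring array medians gave 4, with 3 higher and 1 lower beside 7 and 1. Weights per array gave 754, 1971, 4, 273 and 12 in the order above, with a weight of 7.15 for WT water replicate 1 and 0.10 for WT DSS replicate 2, so few arrays carried these fits. Leaving out both doubted arrays gave 158 for DSS in WT, 56 for TG under DSS and 22 for the interaction, with 1 WT DSS array left and the spread taken from the other groups, so these counts test nothing about WT DSS.

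With the replicate number as a block, 0 genes passed for DSS in WT and 0 for TG under DSS. The replicate numbers are not said to mark a litter, batch or day. The correlations of deviations between arrays of the same number ran from -0.484 to 0.377, which neither shows nor excludes a pairing. The block thus removes degrees of freedom without a known pairing.

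Leaving out 1 array at a time gave 0 to 919 genes for DSS in WT, 0 to 1166 for TG under DSS and 0 to 239 for the interaction, each highest without WT DSS replicate 1. The correlation of the DSS responses ran from 0.007 to 0.493. The number of lists that passed ran from 5 to 15 for DSS in TG.

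Of lists that passed camera, numbering 26, 6, 12, 27 and 23, an estimated correlation left 0 in each comparison, and fry left 7, 0, 0, 1 and 0.

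The sign of some medians reversed. Without both doubted arrays, thus with 1 WT DSS array, tuft cells (-0.12), cell cycle (0.07) and cholesterol synthesis (0.05) did so for DSS in WT, and cholesterol synthesis (-0.03) and enteric neurons (0.05) for the interaction. Without 1 array the adipocyte list at water ran from -0.49 to 0.05. Under DSS the tight junction list kept its sign and ran from 0.03 to 0.84, and the pan-epithelial list ran from -0.02 to 1.05. The absorptive colonocyte list ran from -0.20 to 1.18 there and from -0.13 to 1.17 for the interaction, where pan-epithelial genes ran from 0 to 1.08. Lowest in these 5 ranges was the fit without WT DSS replicate 2, the array with low epithelial values. Cldn2 for DSS in TG ran from -0.22 to 0.04.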

Other observations

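The test of the chromosome segment in this part was written down before it was run, while the genes named here were chosen after their values were seen.

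WT DSS replicate 3 held the largest values of the antimicrobial lectins Reg3b and Reg3g, at 6.99 and 5.83, beside 1.64 and 1.60 in replicate 1 and 1.42 and 0.29 in replicate 2. In the same array the enteroendocrine peptide gene Insl5 read -3.75, the proliferation marker Mki67 read -2.60 and Osr2, a transcription factor, read 4.12. TG DSS replicate 1 was the TG array with inflammatory genes high, with Il1b at 2.32 beside -0.32 and -0.03 in TG DSS replicates 2 and 3, and Mmp13 at 3.31 beside -0.54 and -0.07. Trim30d and Trim12a, members of an antiviral gene family, read -2.51 and -2.25 in TG DSS replicate 1. Trim30d was also low in WT DSS replicates 2 and 3, at -1.99 and -1.55, and Trim12a in WT DSS replicate 2, at -1.15.

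Genes of other tissues stood out in some arrays, and those of the prostate did so in more TG than WT arrays. Pbsn and Tgm4, secretory genes of the prostate, read 4.50 and 4.23 in TG water replicate 2, 4.27 and 3.82 in TG DSS replicate 3, 1.86 and 1.53 in TG DSS replicate 1, and 1.34 and 1.95 in WT water replicate 2. Ucp1 and Adipoq, genes of fat, read 1.96 and 1.22 in WT water replicate 2, where the adipocyte list had a median of 1.06. The neuronal genes Prph, Uchl1, Tafa1 and Gng3 read 1.36, 1.68, 1.85 and 1.06 in WT DSS replicate 2. The male and X-inactivation list had medians from -0.40 to 0.17 over the 12 arrays, and Xist lay between -0.06 and 0.30.

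In no comparison did camera pass the lists for goblet cells, apoptosis and survival, fatty acid oxidation, xenobiotic metabolism, B and plasma cells, mast cells and eosinophils, squamous epithelium, small intestine, or male and X-inactivation. For DSS in WT their medians were -0.39, -0.02, -0.25, -0.45, 0.02, 0.05, -0.09, 0.01 and -0.06.

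Foxred1, Srpr, Fam118b and Tirap, which lie close to one another on a chromosome, read lower in the 3 TG water arrays than in the 3 WT water arrays, from -0.30 to -0.27 against 0.07 to 0.45 for Foxred1. A hypothesis was that a chromosome segment near Foxred1 differs between the genotypes, as can happen around an inserted or selected locus. The test says nothing either way. Among the 20 nearest genes 0 had TG and WT values apart the same way under both treatments, but 0 of the 4 genes themselves met that rule. TG DSS replicate 2 read 0.35, 0.21, 0.55 and 0.50 for them, near the WT arrays. Whether the TG label of this array is right was not tested, and Cldn2 at 0.27 there does not settle it. A wrong label would change what each TG DSS mean and each comparison with it measures, and the cause of the difference stays open.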
